A study of Mus musculus with 6 samples.

How the data were processed

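Testis RNA of 3 heterozygous control and 3 Tmc7 knockout samples was measured by sequencing. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a SMARTER mRNA-Seq kit. Groups and replicate numbers were taken from the sample titles. The authors deposited 1 table of FPKM per gene for all 6 samples, with gene length, position and biotype beside the values. The submitters' processing notes name GRCm38 and mm10 as genome build. The aligner, the counter, the annotation release, strand handling and filters are not given in the sources used here.

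The table had 55711 entries, of which 37384 were above 0 in at least 1 library. Of these entries 54495 had an Ensembl ID that is also in GENCODE M21, and 98.33% of those had identical coordinates, so positions are given in GRCm38. The 1179 entries without an Ensembl ID held 0.52% of the reads. Each deposited FPKM times the gene length was a whole multiple of 1 step per library for 100% of the values above 0, within a tolerance of 0.001 reads, which gave whole reads per gene (pairs, if both ends were sequenced). The implied library sizes equalled median-of-ratios size factors times the geometric mean of the read totals, which was found from the values and is not stated by the authors. Depth was 17059486, 18528046 and 18629233 reads in controls and 19343479, 17397662 and 18140921 reads in the libraries labelled knockout.

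Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, group as the only term), with Benjamini-Hochberg adjusted p under 0.05 and no minimum fold. A log2 difference on this scale understates the change of genes with low values. Means are given with the SD over 3 libraries. The design, the alternatives, 28 gene lists and the rule for naming genes were fixed before the data were examined. The lists held 936 entries, of which 928 matched the table and 802 were tested. They covered spermatogonia, spermatocytes, round and elongated spermatids, acrosome, flagellum, manchette, trans-Golgi trafficking, the TMC family, ion transport, Sertoli, Leydig, myoid, stromal, leukocyte, endothelial, blood, epididymal, and fat and muscle cells, apoptosis, the unfolded protein response, autophagy, cholesterol synthesis, immediate early, heat shock, interferon, mitochondrial and histone genes. Some genes stand in more than 1 list. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. With the estimated correlation 0 lists passed (smallest adjusted p = 0.718). With fry, which asks whether the members of a list move in balance in 1 direction, 0 passed (smallest adjusted p = 0.732), and the mixed fry test, for change in either direction, also gave 0 (smallest adjusted p = 0.737). List levels were compared by an exact two-sided permutation test, whose smallest p with 3 against 3 is 0.1.

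Named genes were Tmc7 and Sypl, the tested TMC family list, the 5 genes of smallest unadjusted p in each direction (since none passed) with a mean of at least 2 FPKM in the higher group and no overlap of the groups, leaving out predicted genes and pseudogenes, up to 4 genes of smallest p in each called list, and the 3 highest in FPKM in 6 lists. Klk1b21, Klk1b27, Srp54a, Srp54c, Tcp10b, Ryr1, the genes given as sharing sequence with or overlapping a named gene, and the genes named only in the closing section were chosen after their values were seen. Sequence sharing was measured as the percent of distinct 31-base words, on either strand, of a gene's GENCODE M21 transcripts that occur in transcripts of other genes. It was measured for Tmc7, Sypl, the genes of smallest p in each direction and the chromosome 7 genes of the closing section. For all other named genes, Hspa1a among them, it was not measured, and their values may include reads of similar copies.

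Alternatives covered pseudocounts of 0.1 and 0.01, other filters on low values, median-of-ratios and quantile normalization, the replicate number as a block, array weights, no trend, a minimum log2 difference of 1, and each library left out. Added after the data were seen were limma-voom on the recovered reads with a mean of at least 10 reads, that read filter with the FPKM test, the late spermatid list level as a covariate, and both control library 3 and library 1 labelled knockout left out. The recovered reads were derived from FPKM, so a count model was not the main test.

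The procedure was tested on simulated data: reads for 18924 genes were drawn with 200 genes changed, 5 times. The changed genes all had a mean of at least 2 FPKM. For the simulated knockout against control comparison, limma-trend called 51.6% of genes changed 2-fold and 91.0% of those changed 4-fold, with 5.7% false among the calls. By limma-voom these were 60.0%, 91.2% and 4.9%. Camera called 5 of 5 shifted lists and 0 of 100 unshifted ones. The noise was drawn independently for each gene, so these counts do not cover lists whose members move together. The simulated shift was larger than the mean log2 difference of any list called in the real data, and smaller shifts were not simulated. In the lists called in the real data, the estimated correlation of members was 0.384 to 0.864. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for reading and plotting.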

Results

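RNA was measured by sequencing in 6 mouse testis libraries, 3 labelled heterozygous control and 3 labelled Tmc7 knockout, on the C57BL6 background. Tmc7 encodes a member of the transmembrane channel-like family, and the series title links its protein to the volume of elongated spermatids and to SYPL1 vesicles of the trans-Golgi network. The deposited values were FPKM, fragments per kilobase of gene length scaled to library size. Between 17059486 and 19343479 reads per library could be worked back from them, and 29316 to 30657 genes were above 0 in each library. The 10 most read genes held 2.84% to 3.2% of the reads, and mitochondrial genes 0.81% to 1.07%. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may in part be technical. Small and ribosomal RNA gene models held 0.1%, 0.1% and 0.1% of the reads in the controls and 0.09%, 0.33% and 0.28% in the libraries labelled knockout. This class joined small nuclear, nucleolar and Cajal body RNA, microRNA, miscellaneous RNA, ribosomal RNA, and mitochondrial ribosomal and transfer RNA, which were not separated.

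The level of Tmc7 itself came first, since it bears on the labels. The gene (ENSMUSG00000042246) lies on the minus strand of chromosome 7 from 118535841 to 118584736 in GRCm38, and its protein-coding transcript has 16 exons. Tmc7 was at 39.1, 37.7 and 37.2 FPKM in the control libraries and at 43.8, 41.9 and 35.1 FPKM in the libraries labelled knockout. The group means were 38.0 ± 0.981 and 40.2 ± 4.57 FPKM (SD, n = 3 each). The difference of 0.08 on the log2(FPKM + 1) scale had a standard error of 0.10, a 95% interval from -0.17 to 0.32 and a limma adjusted p of 0.885. The transcript level therefore does not check the labels of the libraries. The labels do not describe the allele, and a gene total cannot show a small deletion or a frameshift that leaves the transcript in place. Directions given for the libraries labelled knockout rest on the labels alone.

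Sypl, the mouse gene for SYPL1 (ENSMUSG00000020570, chromosome 12 from 32953891 to 32979860), was at 14.2, 12.98 and 12.8 FPKM in controls and at 13.8, 10.5 and 11.6 FPKM in the libraries labelled knockout. Its log2 difference was -0.15 with a standard error of 0.11 (limma adjusted p = 0.868). None of the other 7 tested members of the TMC family and partner list passed (limma adjusted p from 0.868 to 0.997). Tmc5, the neighbour of Tmc7 on chromosome 7, was at 22.1 ± 3.41 FPKM in controls and 21.05 ± 3.75 FPKM in the libraries labelled knockout (SD, n = 3 each). Cib1, a calcium- and integrin-binding protein, was at 53.9 ± 4.88 and 53.9 ± 2.56 FPKM. Cib4 was at 19.7 ± 4.12 and 18.7 ± 3.51 FPKM, and Tmc1, Tmc6, Tmie and Cib2 had group means between 1.002 and 2.61 FPKM. The log2 differences of these 7 genes lay between -0.22 and 0.18.

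**Figure D1:**
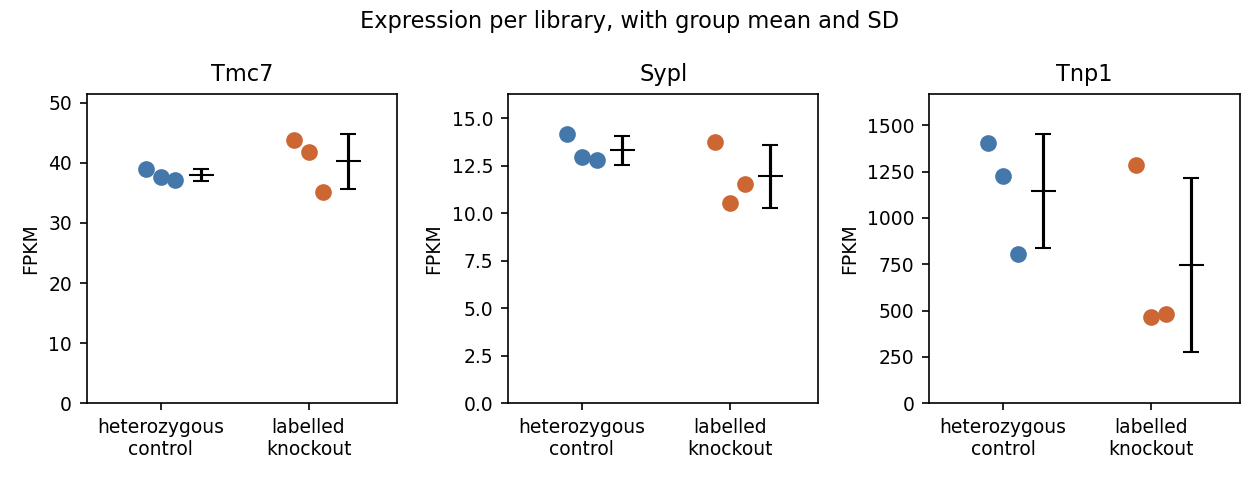
FPKM of Tmc7, Sypl and the spermatid gene Tnp1 in each library (points, blue for heterozygous control, orange for labelled knockout), with the group mean and SD (n = 3) beside them in black. Tmc7 lies between 35.1 and 43.8 FPKM in all 6 libraries, and Tnp1 in library 1 labelled knockout, at 1287 FPKM, lies among the control values.

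The question of the series was which transcripts differ between Tmc7 knockout and heterozygous testes. Of 19168 genes with a mean of at least 0.5 FPKM, 0 were higher and 0 lower in the libraries labelled knockout by limma-trend with Benjamini-Hochberg adjustment at 0.05, and the smallest adjusted p was 0.328. At an unadjusted p under 0.05 there were 284 higher and 457 lower genes, 3.87% of those tested. In 1641 genes (8.56%) all values of one group lay above all values of the other, against 10% by chance. The median standard error of a log2 difference was 0.136. By limma-voom on the recovered reads, a setting added after the data were seen, 1 gene of 20556 was lower and 0 were higher, with 324 higher and 457 lower genes at an unadjusted p under 0.05.

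That gene was Srp54b, which encodes a subunit of the signal recognition particle and lies on chromosome 12 from 55155104 to 55189573 (ENSMUSG00000112449). It was at 5.95, 7.75 and 6.12 FPKM in controls and at 1.43, 2.13 and 1.23 FPKM in the libraries labelled knockout. Its log2 difference was -1.56 with a standard error of 0.16 by limma-trend (adjusted p = 0.328) and -2.09 with a standard error of 0.21 by limma-voom (adjusted p = 0.0195). The value is uncertain, because 89.9% of its 31-base words also occur in transcripts of other genes, 86.1% in Srp54a alone. Srp54a was at 0.769 ± 0.149 and 0.697 ± 0.150 FPKM, and Srp54c at 7.38 ± 0.574 and 6.36 ± 2.03 FPKM (SD, n = 3 each, control and labelled knockout).

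No gene passed the threshold of the limma-trend test, so the genes with the smallest unadjusted p in each direction are given as values. Among the higher values was Sirt2, a NAD-dependent deacetylase on chromosome 7 from 28766735 to 28788661, at 39.9, 36.5 and 36.4 FPKM in controls and 55.5, 55.4 and 59.9 FPKM in the libraries labelled knockout. Its log2 difference was 0.59 with a standard error of 0.09 (adjusted p = 0.693). Mrps27, a mitochondrial ribosomal protein, was at 4.003 ± 0.182 and 5.65 ± 0.731 FPKM, and shares 18.9% of its 31-base words with 6430562O15Rik. Gramd1a, a sterol transfer protein, was at 4.05 ± 0.276 and 5.49 ± 0.432 FPKM. Ap5b1, a subunit of an adaptor complex, was at 8.43 ± 0.0753 and 11.6 ± 1.70 FPKM. Tmem147os, annotated as antisense and uncertain because the strand of counting is not given in the sources used here, was at 2.67 ± 0.463 and 4.19 ± 0.284 FPKM. All 4 had an adjusted p of 0.868.

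Among the lower values, Fam98c on chromosome 7 from 29152510 to 29156234 was at 19.5 ± 1.78 FPKM in controls and 12.6 ± 1.36 FPKM in the libraries labelled knockout, a log2 difference of -0.60. It overlaps the antisense gene 1110035H17Rik, and 48.1% of its 31-base words occur in other genes. Tcp10a, a testis-expressed gene of the t-complex, was at 112 ± 4.61 and 77.5 ± 10.9 FPKM, and is uncertain since 74.1% of its words occur in other genes, 67.2% in Tcp10b. Tcn2, which encodes the vitamin B12 carrier transcobalamin, was at 7.13 ± 0.210 and 5.13 ± 0.419 FPKM. Ndufa12, a subunit of respiratory complex I, was at 33.9 ± 7.29 and 18.3 ± 3.83 FPKM, a log2 difference of -0.85 with a standard error of 0.20, and shares 20.2% of its words with Gm15920. Each of these 4 genes had an adjusted p of 0.868.

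**Figure D2:**
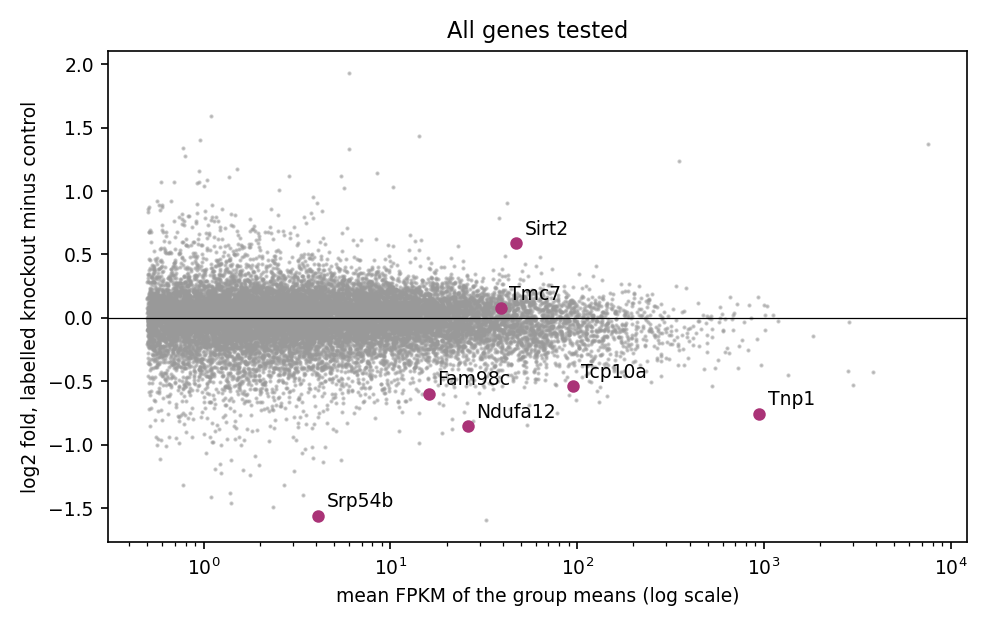
Log2 difference (labelled knockout minus control, on log2(FPKM + 1)) against the mean FPKM of the group means on a log axis, for the 19168 genes tested (grey points), with 7 genes marked in purple. None of the points passed an adjusted p of 0.05 by limma-trend, and Tmc7 lies at 0.08.

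Genes of late spermatids had lower mean values in the libraries labelled knockout, with the lowest list levels in libraries 2 and 3. In the same libraries small and ribosomal RNA gene models held 0.33% and 0.28% of the reads. In the elongating and elongated spermatid list, 39 of 39 tested members were lower and 0 higher, with a mean log2 difference of -0.30. The list passed camera with a preset correlation of 0.01 (adjusted p = 2.09e-06), and the call was lost with an estimated correlation (adjusted p = 0.718). An exact permutation test of the list means, two-sided with 3 libraries against 3, gave p = 0.4, where 0.1 is the smallest it allows. No member passed, either over all genes or adjusted over the list alone. Tnp1, a transition protein that replaces histones in spermatid chromatin, was at 1406, 1226 and 805 FPKM in controls and at 1287, 465 and 481 FPKM in the libraries labelled knockout. Prm1 and Prm2, the protamines that pack sperm DNA, were at 3502 ± 1105 and 3196 ± 875 FPKM in controls and at 2499 ± 1155 and 2417 ± 846 FPKM in the libraries labelled knockout. Tnp2 was at 4394 ± 1105 and 3294 ± 1036 FPKM, Capza3 at 99.4 ± 12.1 and 72.5 ± 23.6 FPKM, Lelp1 at 203 ± 37.0 and 151 ± 49.4 FPKM, and Cylc1, a protein of the sperm head cytoskeleton, at 29.9 ± 1.19 and 22.2 ± 9.36 FPKM.

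The list level was not split by label. Centred on the mean of the 6 libraries, it was 0.38, 0.21 and -0.14 in the controls and 0.30, -0.22 and -0.54 in the libraries labelled knockout. Library 1 labelled knockout thus lay between control libraries 1 and 2, and control library 3 lay nearest to library 2 labelled knockout. At each replicate number the library labelled knockout had the lower level, but the labels do not say that the numbers pair samples. Without library 3 labelled knockout the mean log2 difference of the list was -0.11 and the camera call was lost (adjusted p = 0.154). It was -0.19 without control library 1 and -0.53 without library 1 labelled knockout, where the call was kept. With the replicate number as a block it was -0.30, with a camera adjusted p of 4.51e-16 at the preset correlation.

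Round spermatid genes had 24 of 30 members lower, a mean log2 difference of -0.12 and a camera adjusted p of 0.0124, and an adjusted p of 0.718 with an estimated correlation. The call was also lost without control library 1 (mean -0.06, adjusted p = 0.483), without library 2 labelled knockout (mean -0.06, adjusted p = 0.412), without library 3 labelled knockout (mean -0.08, adjusted p = 0.141) and with quantile normalization (mean -0.07, adjusted p = 0.0593). Without library 1 labelled knockout the mean was -0.22. Zpbp, an acrosomal zona-binding protein, was at 52.8 ± 2.74 and 43.6 ± 9.46 FPKM, Spaca1 of the acrosomal membrane at 85.2 ± 7.92 and 70.0 ± 16.7 FPKM, Dpy19l2, which anchors the acrosome to the nucleus, at 81.1 ± 3.47 and 69.8 ± 10.3 FPKM, and Hook1 of the manchette at 57.8 ± 6.29 and 45.5 ± 13.2 FPKM (control and labelled knockout, SD, n = 3 each). The acrosome list had 32 of 47 members lower, a mean of -0.09 and a camera adjusted p of 0.0533. It passed as lower without control library 2 (adjusted p = 0.0377), without control library 3 (adjusted p = 0.00955), without library 1 labelled knockout (mean -0.17, adjusted p = 0.00139), without both of the latter (adjusted p = 0.000539) and with the replicate number as a block (adjusted p = 0.0128), all at the preset correlation. With an estimated correlation in all 6 libraries it had an adjusted p of 0.718. The mean was -0.04 without control library 1, -0.05 without library 2 labelled knockout and -0.06 without library 3. Its 3 members with the highest FPKM, Ccdc136, Lypd4 and Actl9, were at 412 ± 39.9, 285 ± 25.1 and 272 ± 37.9 FPKM in controls and at 391 ± 51.6, 286 ± 13.1 and 259 ± 45.02 FPKM in the libraries labelled knockout.

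Camera with the preset correlation called 4 lists as higher in the libraries labelled knockout, the Sertoli list (24 of 30 members higher, mean 0.15, adjusted p = 0.000153), the peritubular myoid list (15 of 16, mean 0.20, adjusted p = 0.000153), the macrophage and leukocyte list (20 of 20, mean 0.22, adjusted p = 0.000106) and the immediate early genes (14 of 16, mean 0.21, adjusted p = 0.00266). Each had an adjusted p of 0.718 with an estimated correlation, and no member passed by either adjustment. Exact permutation tests of the 4 list means gave p between 0.3 and 0.4.

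Among Sertoli genes, Clu, which encodes clusterin, was at 230 ± 3.50 FPKM in controls and 257 ± 33.9 FPKM in the libraries labelled knockout. Aard was at 101 ± 6.64 and 121 ± 18.97 FPKM, Amhr2, a receptor for anti-Müllerian hormone, at 96.9 ± 5.25 and 114.5 ± 14.2 FPKM, and Sox9, a transcription factor of Sertoli identity, at 4.85 ± 0.691 and 6.40 ± 1.36 FPKM. Gstm6 was at 16.5 ± 2.07 and 22.2 ± 4.59 FPKM, and Fshr, the receptor for follicle-stimulating hormone, at 1.16 ± 0.320 and 1.88 ± 0.517 FPKM. Of the smooth muscle genes of peritubular cells, Acta2 was at 30.4 ± 2.41 and 40.4 ± 8.86 FPKM, Flna at 7.41 ± 0.393 and 9.92 ± 2.83 FPKM, Myh11 at 5.87 ± 0.362 and 7.56 ± 1.88 FPKM and Cnn1 at 1.73 ± 0.0490 and 2.24 ± 0.437 FPKM. The macrophage genes C1qb, Csf1r, Fcer1g and Cd68 were at 9.30 ± 0.124, 2.81 ± 0.196, 1.86 ± 1.02 and 1.39 ± 0.194 FPKM in controls and at 11.2 ± 1.65, 3.88 ± 1.20, 3.003 ± 0.612 and 2.43 ± 1.08 FPKM in the libraries labelled knockout. Junb, Ier2, Dusp1 and Hspa1a, which respond to acute stimulation or stress, were at 2.71 ± 0.614, 4.24 ± 0.671, 3.01 ± 0.116 and 0.939 ± 0.161 FPKM and at 4.49 ± 2.23, 5.78 ± 1.46, 3.70 ± 0.644 and 1.47 ± 0.397 FPKM.

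The Sertoli level was -0.13, -0.11 and 0.01 in the controls and -0.15, 0.15 and 0.23 in the libraries labelled knockout, with library 1 labelled knockout below all 3 controls. Libraries 2 and 3 labelled knockout, with the highest Sertoli levels, were also those with 0.33% and 0.28% of reads on small and ribosomal RNA gene models. The Sertoli call was lost without library 3 labelled knockout (mean 0.07, adjusted p = 0.141) and the myoid call without library 2 (mean 0.09, adjusted p = 0.0619). The immediate early call was lost without library 2 labelled knockout (mean 0.05, adjusted p = 0.451), without control library 1 (mean 0.14, adjusted p = 0.0831) and with a mean of at least 2 FPKM (mean 0.17, adjusted p = 0.0606). The leukocyte mean was 0.15 without library 3 labelled knockout (adjusted p = 0.0393). Without library 1 labelled knockout the Sertoli, myoid, leukocyte and immediate early means were 0.26, 0.31, 0.36 and 0.34. The count of called lists went from 6 to 10 when control library 3 and library 1 labelled knockout were both left out, a setting added after the data were seen.

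**Figure D3:**
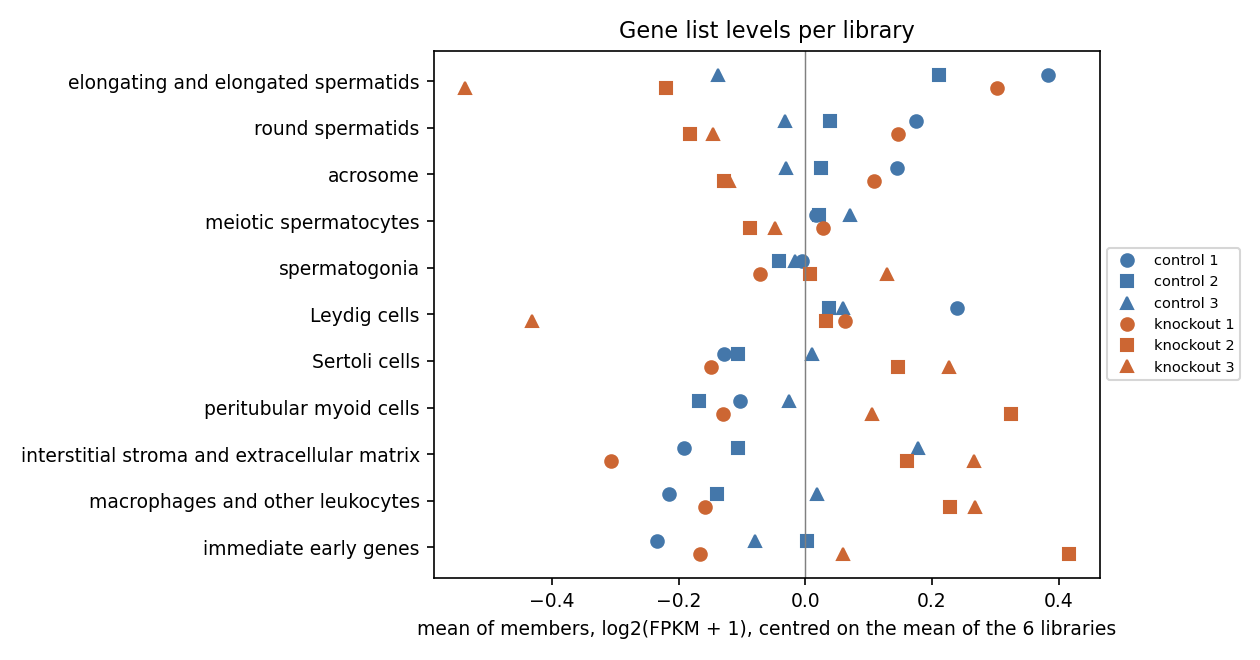
Level of 11 gene lists in each library, as the mean of the members on log2(FPKM + 1) centred on the mean of the 6 libraries (blue for heterozygous control, orange for labelled knockout, 1 symbol per replicate number). In the elongated spermatid list, library 1 labelled knockout (0.30) lies among the controls and control library 3 (-0.14) lies beside library 2 labelled knockout (-0.22).

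Leydig cell genes, which make steroid hormones, had 17 of 25 members lower with a mean of -0.22, a median of -0.16 and a camera adjusted p of 0.13. The list passed as lower without library 2 labelled knockout (mean -0.30, adjusted p = 0.00634), and its mean was -0.07 without library 3 (adjusted p = 0.805). With an estimated correlation in all 6 libraries it had an adjusted p of 0.718. The largest differences in it were those of the kallikreins Klk1b27 and Klk1b21, at -1.49 and -1.12, both with their highest values in control library 1. Sequence sharing was not measured for these kallikreins, so their values are uncertain. Insl3 was at 115 ± 10.1 and 99.3 ± 31.5 FPKM, Cyp17a1 at 123 ± 22.6 and 116 ± 51.8 FPKM, and Ptgds at 40.4 ± 4.61 and 53.0 ± 30.8 FPKM. Library 3 labelled knockout had the lowest value of all 6 libraries for each of these 3 genes, at 68.3, 60.8 and 17.7 FPKM. The stroma, endothelial and interferon response lists had means of 0.08, 0.08 and 0.08 and adjusted p of 0.36, 0.213 and 0.273. Stroma passed as higher without control library 3 (mean 0.19, adjusted p = 0.00955) and without library 1 labelled knockout (mean 0.25, adjusted p = 0.000569), but had a mean of -0.03 without library 3 labelled knockout. The endothelial list passed without library 1 labelled knockout (mean 0.17, adjusted p = 0.0208), but had a mean of 0.02 without library 2 and of 0.03 without library 3. The interferon mean was 0.03 without library 3 labelled knockout. Without library 1 labelled knockout and control library 3 the stroma, endothelial and interferon lists all passed (adjusted p = 3.88e-07, 0.0126 and 0.037 at the preset correlation). With an estimated correlation in all 6 libraries these 3 lists had an adjusted p of 0.875, 0.718 and 0.718. Spermatocyte genes had 25 of 41 members lower (mean -0.07, adjusted p = 0.13; -0.05 without library 2 labelled knockout, adjusted p = 0.39), and spermatogonia genes 13 of 23 higher (mean 0.04, adjusted p = 0.432).

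Genes of the trans-Golgi network and vesicle trafficking, the compartment named in the series title, had 48 of 83 members higher and 35 lower, with a mean of 0.02 (camera adjusted p = 0.44). Vps26a, a retromer subunit, was at 160 ± 4.42 FPKM in controls and 135 ± 18.7 FPKM in the libraries labelled knockout, Arf1, a small GTPase of the Golgi, at 102 ± 6.31 and 111 ± 8.57 FPKM, and Ap1m1 of the clathrin adaptor AP-1 at 74.97 ± 6.19 and 83.7 ± 9.01 FPKM. In the ion transport and cell volume list 41 of 74 members were higher, with a mean of 0.02 and an adjusted p of 0.393. Catsperz of the sperm calcium channel was at 280 ± 26.6 and 270 ± 38.9 FPKM, Atp1a4, the sperm sodium pump, at 208 ± 24.4 and 181 ± 55.5 FPKM, and Atp1b3 at 199 ± 30.1 and 169 ± 42.8 FPKM.

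The flagellum list had 32 of 58 members lower (mean -0.04, adjusted p = 0.692) and the manchette list 24 of 44 (mean -0.05, adjusted p = 0.581). The apoptosis, unfolded protein response and autophagy lists each had a mean of 0.02, with adjusted p of 0.569, 0.583 and 0.36. Heat shock and oxidative stress genes had a mean of -0.05 (adjusted p = 0.54), mitochondrially encoded transcripts of -0.08 (adjusted p = 0.305), and replication-dependent histones of 0.13 (adjusted p = 0.153). The histone mean was 0.04 without library 3 labelled knockout, and the mitochondrial mean was -0.03 without control library 3 and -0.04 without library 3 labelled knockout. With 1 library left out, the mean of each of the 28 lists moved by more than 1.5 times or turned sign in at least 1 setting, and the means of 10 lists turned sign. These were the flagellum, manchette, spermatogonia, stroma, TMC family and cholesterol lists without library 3 labelled knockout (0.022, 0.009, -0.011, -0.033, 0.035 and 0.021), the ion transport, autophagy and blood lists without library 2 (-0.011, -0.002 and 0.099), and the epididymal list without control library 1 (0.015). The TMC family list also turned without control library 1 (0.021), the cholesterol list without control library 2 (0.023) and the blood list without control library 3 (0.158). The blood, epididymal and TMC family lists had means of -0.27, -0.05 and -0.01 and adjusted p of 0.36, 0.794 and 1. The blood list passed as lower without control library 2 (mean -0.79, adjusted p = 0.0456) and without library 3 labelled knockout (mean -0.88, adjusted p = 0.0393), and had a mean of 0.16 without control library 3. With an estimated correlation in all 6 libraries it had an adjusted p of 0.718. Cholesterol synthesis had a mean of -0.01 against a median of 0.01 and a direction of higher in camera (adjusted p = 0.812), and the list of adjoining fat and muscle had a mean of -0.11 and a median of -0.01 against the same camera direction (adjusted p = 0.624). In that last list Ryr1, the calcium release channel of muscle, on chromosome 7, was at 0.879 ± 0.0952 and 1.70 ± 0.330 FPKM. It passed when adjusted over the 6 tested genes of that list alone (limma adjusted p = 0.0288). It was the only one of 802 tested list entries to pass within its own list, while 0 passed over all genes tested. The adjustment within a list does not cover the 28 lists, so 1 such call may be due to chance.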

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

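The settings added after the data were seen were limma-voom, the read filter, the late spermatid covariate and leaving out control library 3 with library 1 labelled knockout. Under 20 alternatives the count of higher genes stayed at 0, and that of lower genes was 0 except for 1, Srp54b, by limma-voom; the cause was not tested. The Tmc7 difference ranged from -0.001 (without control library 3 and library 1 labelled knockout) to 0.17, with adjusted p from 0.772 to 1. Of 28 lists, 6 passed, 10 passed without control library 3 and library 1 labelled knockout, and 0 passed with an estimated correlation or with fry, which allow for the correlation of members seen in these libraries. Leaving out each library in turn gave 4 to 9 lists, 0 genes in either direction and Tmc7 values within the range above. Of 60 named genes, 15 changed sign under at least 1 setting without passing, as did 11 lists. In simulation 91.0% of 4-fold changes but only 51.6% of 2-fold changes were called, all in genes with a mean of at least 2 FPKM. Changes in genes below that mean, and spread shared by many genes of a library, were not simulated.

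Counts at an unadjusted p under 0.05, 284 higher and 457 lower, were 1499 and 1992 without library 1 labelled knockout, 1205 and 2148 without that library and control library 3, 916 and 1260 with array weights (0.419 for that library, the lowest), 635 and 701 with no filter, and 156 and 262 with a mean of at least 2 FPKM, where fewer genes were tested. Without control library 2 there were 182 higher, and without library 2 labelled knockout 273 lower. With the replicate number as a replicate block there were 0 higher and 0 lower genes past the threshold, 405 and 1006 at an unadjusted p under 0.05, a Tmc7 difference of 0.08 and 7 lists. After centring within groups, libraries with the same number correlated at 0.286, 0.041 and 0.198, the highest value of each control library. Library 2 labelled knockout, however, correlated best with control library 3 (0.17). Values centred within 3 libraries depend on each other, so these correlations cannot decide whether the numbers pair the samples.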

Other observations

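All tests in this part were chosen after the results they bear on had been seen, except the count of splits for genes past the threshold, which was part of the design although its expected outcome was written down later, and the test of shared sequence, whose bound was set before the shares were computed but whose 2 parts were joined afterwards. The hemoglobin genes did not separate the 2 groups, but followed the replicate number, with library 3 highest and library 2 lowest in both groups. The labels do not say what the numbers share. Hba-a1 was at 5.09, 0.399 and 27.3 FPKM in controls and at 0.977, 0.213 and 29.4 FPKM in the libraries labelled knockout, and Hbb-bs at 5.30, 0.07 and 10.8 and at 1.38, 0.30 and 16.9 FPKM. The kallikrein genes of the Leydig list were highest in control library 1, where Klk1b21, Klk1b27 and Klk1b26 were at 13.7, 8.68 and 3.25 FPKM against at most 6.09, 2.63 and 0.413 FPKM in the other 5 libraries. Sequence sharing was not measured for these kallikreins or the hemoglobin genes, so the values within each set may rest in part on the same reads. Gm23935, a microRNA gene model on chromosome 16, was at 4437, 3528 and 3089 FPKM in controls and at 3674, 18296 and 12540 FPKM in the libraries labelled knockout.

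With 10 splits of the 6 libraries into 3 and 3, the design cannot give a share under 0.1. The real split gave 0 genes past the threshold, a count that all 10 splits reach, and the highest other gave 10. At an unadjusted p under 0.05 it gave 741 genes, reached in 5 splits, with 3530 as the highest other. It gave 6 lists, reached in 7 splits, with 11 as the highest other, and by limma-voom 1 gene, reached in 5 splits, with 515 as the highest other. The highest counts all belong to the split that sets control libraries 1 and 2 and library 1 labelled knockout against the rest, which points to a structure of the samples other than the labels.

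Of 6 somatic lists, 2 ran against the late spermatid level across the 6 libraries with an adjusted p under 0.05, the Sertoli list (Pearson's r -0.97, exact permutation p = 0.00278, adjusted 0.025 over 27 relations; Spearman's rho -0.943, p = 0.0167, adjusted 0.0752) and the leukocyte list (r -0.96, p = 0.00139, adjusted 0.0188; rho -1, p = 0.00278, adjusted 0.0375), with r of -0.955 and -0.93 without the 2 libraries farthest from the median, and so did the interferon response list, which is no cell type list (r -0.991, exact permutation p = 0.00139, adjusted 0.0188; rho -1, p = 0.00278, adjusted 0.0375; r -0.996 without those libraries). The stroma, endothelial and myoid lists did not pass (r -0.942, -0.903 and -0.718, adjusted permutation p = 0.0796, 0.0796 and 0.164; rho -0.886, -0.886 and -0.714), and the Leydig list went the other way (r 0.833, exact permutation p = 0.00694, adjusted 0.0468; rho 0.943, p = 0.0167, adjusted 0.0752), a relation that rests on the 2 farthest libraries, since r was 0.349 without them. The slope of a gene on the late spermatid level had a Spearman's rho of -0.113 with length, in protein-coding genes outside the lists. The 1830 of these between 903.5 and 1994.5 bases, the middle lengths of the late list, had a median slope of 0.046, and 16.2% reached 0.5. This argues against length as the whole account in that range, and other lengths were not covered. In median slope, the Leydig list lay above the Sertoli list by 0.688 ± 0.246 (SE), or 0.497 ± 0.178 without library 3 labelled knockout. The spermatocyte list did so by 0.479 ± 0.093 (0.406 ± 0.131) and the spermatogonia list by 0.239 ± 0.114 (0.395 ± 0.108). These SEs come from resampling genes as if independent, and do not measure the spread between libraries. They cannot decide whether a lower share of late spermatids is the whole account. The Sertoli, myoid, stroma and leukocyte lists had the negative median slopes that a lower share needs (-0.41, -0.46, -0.591 and -0.454, SE over genes 0.063, 0.074, 0.131 and 0.108). The endothelial slope was -0.229 with an SE of 0.131, and -0.449 with an SE of 0.15 only without library 3 labelled knockout. For the 5 other somatic lists as a set, a lower share therefore cannot be told apart from other explanations. An exchange of labels between library 1 labelled knockout and control library 3 may also be behind the 10 genes of that split, and cannot be told apart since Tmc7 transcript does not separate the groups; an effect of genotype on late spermatids stays open as well.

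In limma-voom, 7 of 116 genes between 30 and 40 Mb on chromosome 7 had an unadjusted p under 0.01 (0.39 expected, exact hypergeometric p = 1.24e-07 for the most clustered window of the scan, and p = 0.001, the smallest that 1000 permutations of gene positions can give, over all windows), but 7 of 10 splits had a window with such a permutation p under 0.05. Both tests treat neighbouring genes as independent. Among the 7 were Gm6605, Gm5591, 1700010N08Rik, Gm1988 and Gm6124, which lie between 38446621 and 39223175 and reached at most 1.462 FPKM in a library. Gm1988 had 82.8% of its 31-base words in Gm5591, so both p-values may be too small. Between 25 and 45 Mb, 13 of 342 genes had an unadjusted p under 0.01, among them Sirt2, Ryr1, Fam98c, Gramd1a and Klk1b5, none past the threshold (limma adjusted p from 0.298 to 0.858). Tmc7 lies outside that span, from 118535841 to 118584736 on the same chromosome. DNA carried along with the Tmc7 allele cannot be told apart from other explanations, since 0 of 264 genes within 10 Mb of Tmc7 had an unadjusted p under 0.01 where 0.89 were expected, too few to decide. Reads shared between gene copies may contribute, since only 3 of the 13 genes, Sirt2, Ryr1 and Gramd1a, had under 10% of their 31-base words in other genes. That count is exactly at the bound of the test. Among protein-coding genes with a symbol of their own, 1 of 70 between 30 and 40 Mb had such a p (0.18 expected, exact hypergeometric p = 0.164). Between 25 and 45 Mb 5 of 237 did (0.60 expected, exact hypergeometric p = 0.000315). That span was drawn after the genes were seen, so its p is low by selection and decides nothing. Of the 5, Fam98c and Klk1b5 had 48.1% and 27.8% of their words in other genes. Sirt2, Ryr1 and Gramd1a share little, so between 25 and 45 Mb sharing is not shown to be the whole account. Of these, only Gramd1a lies between 30 and 40 Mb, the window that gave the clustering. Its other genes with such a p, Gm12763, Gm6605, Gm5591, 1700010N08Rik, Gm1988 and Gm6124, had 24.7% to 90.8% of their words in other genes. Blocks that segregate among the animals without regard to genotype, if the libraries came from separate animals, are a further hypothesis, since 4 of 10 splits, the real one included, had a window as clustered, among them chromosome 8 from 30 to 40 Mb, where 1700104B16Rik was at 0.505, 21.9 and 0.649 FPKM in controls and 44.97, 17.1 and 0.355 FPKM in the libraries labelled knockout. Shared sequence was not measured for the windows of the other splits, so shared reads cannot be told apart from such blocks there.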
